A study of Mus musculus with 6 samples.

How the data were processed

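Gene expression was measured in colonic epithelium of 6 male mice, 3 wild-type and 3 miR-31 knockout, with 1 Agilent one-colour array per mouse. Per the study's design note, the tissue was separated by flow into TRIzol, and per the labels RNA was prepared with that reagent and cDNA labelled with Cy3 was made from linearly amplified RNA. The gate of the flow separation is not given in the sources used here, and neither are the strain, the age and the way the knockout was made. The deposited scanner files give the intensity of each spot. Per the file headers they come from Agilent Feature Extraction 11.5.1.1, whereas the submitters' processing notes name version 10.7. The deposited processed intensity is background-subtracted and detrended over the slide, dim spots carry a small positive value, and the values are not normalized between arrays. The deposited series table holds the same processed intensity for each probe, on a linear scale: 99.7% of its values lay within 0.01 log2 units of the scanner values averaged over the spots of a probe. Its column medians were 231, 234 and 247 in wild-type replicates 1 to 3 and 259, 228 and 241 in knockout replicates 1 to 3. Its scale and direction are therefore known, and no centring was found.

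Each array held 62976 spots, of which 3671 control spots were left out. The remaining 59305 spots belong to 56605 probes. Gene names came from matching each probe's RefSeq accession to an NCBI RefSeq gene table of the mouse assembly GRCm38.p6. The array design names mm9, so no coordinates are printed and the table served only for names, chromosomes and gene order. A symbol was found for 33767 probes, and the other 22838 keep the name of the array design. The processed intensity was taken as log2 and the 75th percentile of the array over all non-control spots was subtracted. Spots that the extraction software marked as non-uniform, as population outliers or by hand were left out, spots of 1 probe were averaged, and saturated spots would have been kept, although 0 were saturated on any array. Non-uniform spots made up between 4.82% and 17.2% of the non-control spots per array, and 24.9% of spots were marked on at least 1 array, which removed 4359 features from the test. Marking fell more on bright spots: 34.2% were marked, over all arrays, among spots of probes with a mean above the 75th percentile. A probe was tested when it was well above background on at least 3 of the 6 arrays and had at least 2 unmarked arrays in each group. For a gene with several probes, the probe with the highest mean over all arrays was used. This left 27916 features, 15251 with a gene symbol and 12665 under an accession or locus name only.

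Knockout and wild-type arrays were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 (with statmod 1.5.0 and the data.table package, version 1.17.8) with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all 27916 features with a threshold of 0.05. A looser count used an unadjusted p under 0.05 and a log2 change of at least 1. Errors are standard errors (SE) of the log2 change from limma, or standard deviations (SD) between arrays, and n gives the wild-type and knockout arrays, 3 and 3 unless stated. A gene with no probe well above background on any array of a group has only a bound there. It is given as "at least N-fold", from the brighter group's mean over all its arrays against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The 39 gene lists, with 880 genes, were written before the data were examined, as were the comparisons, the rule for named genes and most alternatives. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, in the form that works from each gene's limma statistic, against the features with a gene symbol. That background was chosen after a first run against all features, which called 10 lists higher and 0 lower and is kept as an alternative. Camera with an estimated correlation and fry, a self-contained rotation test, were alternatives. The form with an estimated correlation also takes its degrees of freedom from the arrays rather than the genes, so a call can be lost without any correlation.

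Named genes are, per direction, the 12 genes with the largest log2 change among those past the threshold whose 3 knockout arrays all lie above or all below the 3 wild-type arrays, without genes known only by a clone, locus, Riken, Gm or accession name. Where fewer than 12 passed, genes with the smallest unadjusted p among those at least 2-fold apart without overlap filled the list. Up to 4 members of each list described, those with the smallest unadjusted p, were also named, apart from 2 members that are not reported here, along with a fixed set of 10 genes: Il7r, Il17ra, Il6st, Axin1, Gsk3b, Dkk1, Smad3, Smad4, Bmpr1a and Lgr5, of which Dkk1 was not in the tested set. Which 23 lists were described with their members was chosen after the list results were seen. The planned test of genes with a miR-31 seed site was not run, because it needs 3' UTR sequences, which were not used here.

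All 6 arrays shared 1 slide and 1 scan date. Per the positions in the deposited files, every knockout array lay in slide row 1 and every wild-type array in slide row 2, so row and genotype cannot be told apart. Slide columns were 1, 2 and 4 for wild-type replicates 1 to 3 and 1, 2 and 3 for knockout replicates 1 to 3, and the column was tried as a random block. Replicate numbers follow the order of deposition and pair no mice. The alternatives were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization alone, scaling by the median, the deposited series table, no filter on dim probes, a filter requiring all 6 arrays, the mean of a gene's probes, limma's trend and robust variance, array weights, the slide column and leaving out each array in turn. The deposited files give no mean spot signal, so normexp used the median spot signal with the median local background. Keeping the spots marked as outliers, and a fixed block from the animal numbers in the sample titles, were added after the data were seen. The block sets wild-type replicates 1 and 2 and knockout replicates 1 and 2, whose numbers lie within 10 of another's, against the third replicates. The numbers of the third replicates also lie far from each other, so the block need not mark a batch. The number of arrays limits the precision of every value.

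The gene test was tested on simulated data: 20 simulated sets drawn from the means and spreads of the 27916 features, with 200 genes changed in each. Limma called 3.5% of genes changed 1.5-fold, 47.0% of those changed 2-fold, 95.4% of those changed 4-fold and 98.9% of those changed 8-fold, with on average 8.5 unchanged features called per set. A list shifted by 0.3 on the log2 scale was called in 16 of the 20 sets, and 3 of 760 tests of unshifted lists were called. The simulated genes varied independently, whereas genes of the real lists can correlate, with an estimate of 0.84 for interferon genes. The simulation therefore does not give the rate of false list calls in the real data.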

Results

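The series compared colonic epithelium of 3 wild-type male mice with that of 3 male mice lacking miR-31, a microRNA, to describe how the loss of miR-31 alters the pattern of gene expression in the mouse colon. Between 66.6% and 75.6% of probes were well above background per array, and the 75th percentile of signal ranged from 3005 to 3539. Array signals correlated at Pearson's r of 0.987 to 0.992 within the wild-type group, 0.984 to 0.989 within the knockout group and 0.982 to 0.988 between groups, across probes. The first principal component, with 38.4% of the variance over 24052 features, placed wild-type replicates 1 and 2 at -41.0 and -39.0, wild-type replicate 3 at -7.58 and the knockout arrays between 21.5 and 34.1.

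No probe on the array measured Mir31 itself or its host transcript Mir31hg, so the deletion was not checked by these data. Among protein-coding genes close to Mir31 on chromosome 4, Mtap, the enzyme that salvages methionine from methylthioadenosine, had a log2 change of 0.16 ± 0.19 (SE, n = 3 and 3), and Klhl9 one of 0.01 ± 0.12. Hacd4 had a log2 change of -0.92 ± 0.28 that did not pass (adjusted p = 0.331). None of the 5 measured members of this neighbourhood list passed the test.

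A small group of genes changed strongly. Of 27916 features, 41 were higher and 17 lower in knockout epithelium at an adjusted p under 0.05 (limma), of which 23 and 10 carry a gene symbol. Zfp979, a zinc finger protein gene, and Ifi202b, an interferon-inducible DNA-binding protein gene, were not well above background on any wild-type array and rose at least 84.8-fold and at least 85.0-fold (adjusted p = 0.000109 and 0.0006). A second probe of Zfp979 gave a smaller log2 change, 4.12 ± 0.59. Sfrp1, which encodes a secreted antagonist of Wnt ligands, rose at least 5.85-fold from below background (adjusted p = 0.0453). This call was lost in 4 of the 6 fits with 1 array left out and under 3 other settings, with log2 changes between 1.44 and 5.50. Among the named genes that fell, Pbp2, a phosphatidylethanolamine-binding protein gene, had the largest change, a log2 change of -3.57 ± 0.30 (SE, n = 3 and 3). It was well above background on only 1 of the 3 knockout arrays. Knockout replicates 1 and 2, at -7.38 and -6.81, lay below the lowest signal of probes well above background there, -6.12 and -6.59. The size of the fall is therefore uncertain, with log2 changes between -3.80 and -1.86 over the alternatives.

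Of the 12 named genes that rose, 5 are zinc finger genes. Besides Zfp979, Rex2 rose at least 5.51-fold and Zfp981 at least 5.79-fold, both from below background in wild-type tissue, Zfp600 rose at least 4.91-fold and Zfp963 by a log2 change of 2.42 ± 0.16 (SE, n = 3 and 3). Zfp600, Zfp981, Rex2 and Zfp979 lie on chromosome 4 within a few tested genes of one another and belong to a family of related sequences, so that signal shared between members cannot be ruled out. This cluster lies 519 to 523 tested genes from Mir31. Acot12, an acetyl-CoA thioesterase gene, rose at least 4.65-fold. Afm, which encodes the plasma vitamin E-binding protein afamin, rose by a log2 change of 2.96 ± 0.17 from a mean of -2.26 ± 0.18 (SD, n = 3) to 0.70 ± 0.25 (SD, n = 3), relative to the 75th percentile. F2r, the thrombin receptor gene, rose by 2.71 ± 0.23, and Cma2, a mast cell chymase gene, by 2.82 ± 0.19 on the log2 scale (SE, n = 3 and 3). Pira2, a paired immunoglobulin-like receptor gene of myeloid cells, rose at least 3.62-fold by its tested probe. A second probe had a log2 change of 1.06 ± 0.61 (unadjusted p = 0.127), so the change of Pira2 depends on the probe. The tested probes of Pira2 and Zfp600 were not well above background on any wild-type array, although another probe of each gene was, so their bounds are those of the tested probe. Of these 12 genes, Sfrp1, Rex2, Acot12, F2r and Pira2 lost the call with at least 1 array left out, Acot12 also without the filter on dim probes and Pira2 with the mean of its probes. Zfp600 lost it with the spots marked as outliers kept, where a brighter probe was used (log2 change 0.32, adjusted p = 0.596). Adjusted p-values of these 12 genes lay between 0.000109 and 0.0453.

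**Figure D1:**
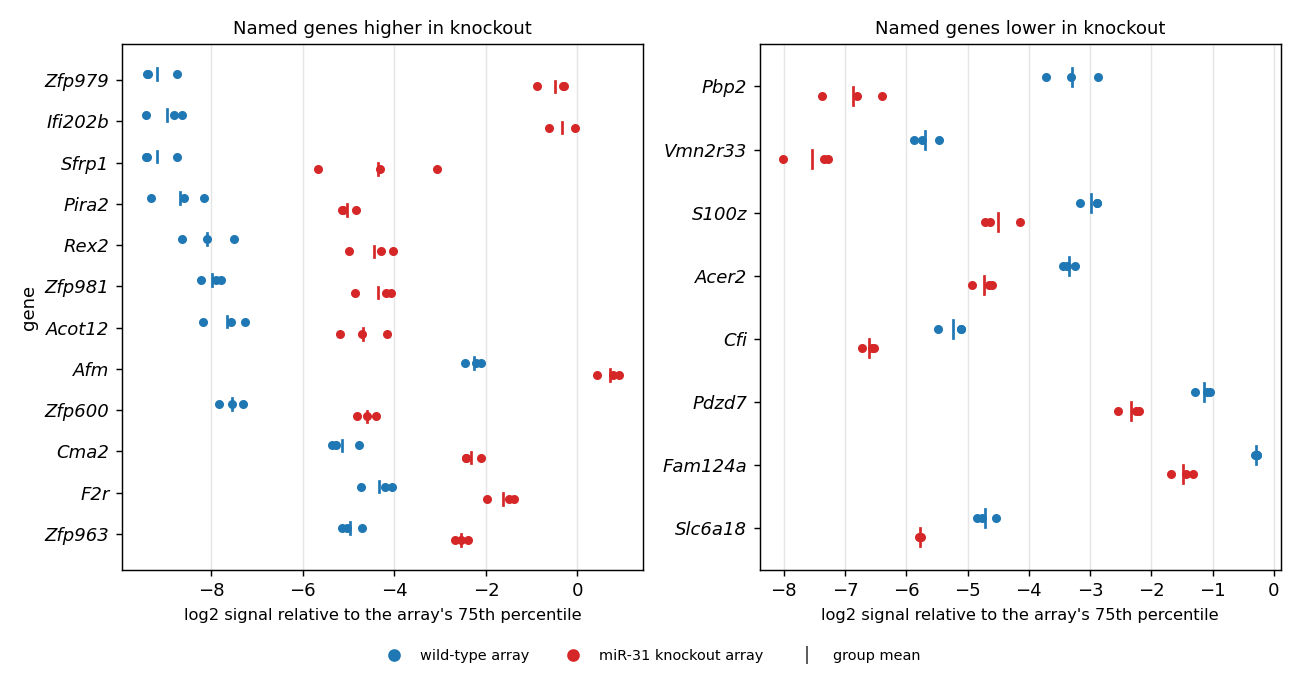
Signal of the 12 named genes higher and the 8 named genes lower in knockout epithelium, as log2 signal relative to the array's 75th percentile (x axis), with 1 gene per row. Points are arrays (blue wild-type, red knockout), short vertical lines are group means; the 2 groups do not overlap for any of these genes, and Ifi202b has 2 knockout points because 1 spot was left out.

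Fewer named genes fell. After Pbp2, Vmn2r33, a vomeronasal receptor gene, and Cfi, which encodes complement factor I, fell at least 1.71-fold and at least 2.31-fold to below background. S100z, a calcium-binding protein gene, had a log2 change of -1.52 ± 0.19, and Acer2, the alkaline ceramidase of the Golgi, one of -1.38 ± 0.14 (SE, n = 3 and 3). Pdzd7, Fam124a and Slc6a18, a neutral amino acid transporter gene, had log2 changes of -1.19 ± 0.14, -1.19 ± 0.13 and -1.07 ± 0.12. Adjusted p-values of these 8 genes lay between 0.00801 and 0.0426. Each lost the call with at least 2 of the 6 arrays left out in turn, Pdzd7 and Slc6a18 with any of them. All but Pbp2 also lost it without the filter on dim probes. Vmn2r33 and Cfi lost it with normexp and with quantile normalization, Slc6a18 with normexp and with trend and robust variance, S100z and Slc6a18 with the animal number block, and S100z and Pdzd7 with the mean of a gene's probes. Slco1c1, Amhr2, Olfr1395 and Stc2 filled the list without passing, with adjusted p-values of 0.0568, 0.0645, 0.0696 and 0.0721. Slco1c1 did pass under 5 alternatives (lowest adjusted p = 0.0042), Amhr2 and Stc2 under 3 each and Olfr1395 under 2. Acer2 is also carried by the chromosome 4 region of Mir31, 22 tested genes away. A second probe of Acer2 moved the same way, with a log2 change of -1.52 ± 0.30. A second probe of Pdzd7 went the other way, at 0.56 ± 0.17, so the change of Pdzd7 depends on the probe.

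All 58 called features had no overlap between groups. Over all features the groups did not overlap for 18.0%, against 10% expected by chance with 3 against 3. At an unadjusted p under 0.05, 3000 features differed, and with a change of at least 2-fold 222 were higher and 204 lower. Leaving out wild-type replicate 1, 2 or 3 lowered the calls to 22, 28 and 37, leaving out knockout replicate 2 lowered them to 30, and leaving out knockout replicate 3 raised them to 116. Slide row and genotype could not be told apart.

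Genes reported to be targets of miR-31 were compared next, as the list closest to the loss of the microRNA. The arrays measure RNA, so an effect on protein alone would not show, and the planned test of seed sites was not run. Of 36 listed genes 30 were measured, and 0 passed over all genes or adjusted over the list alone. Their median log2 change was 0.07, with 20 members above and 10 below 0, and the list was not called (camera adjusted p = 0.123, and adjusted p = 0.664 with an estimated correlation). Krt16, an injury-associated keratin gene, had a log2 change of -0.45 ± 0.13 and E2f2, a cell cycle transcription factor gene, one of 0.39 ± 0.17 (SE, n = 3 and 3). At an unadjusted p under 0.05, 1 member was higher and 2 were lower.

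The cytokine receptor and Wnt, BMP and TGF-beta signalling genes fixed in advance did not pass either. Il7r had a log2 change of -0.49 ± 0.41, Il6st of 0.34 ± 0.24 (SE, n = 2 and 3) and Il17ra of 0.10 ± 0.19 (SE, n = 2 and 2). Axin1 and Gsk3b, both members of the beta-catenin destruction complex, had log2 changes of 0.11 ± 0.12 and 0.04 ± 0.12. Smad3, Smad4 and Bmpr1a, which carry TGF-beta and BMP signals, had log2 changes of 0.24 ± 0.17 (SE, n = 2 and 3), -0.44 ± 0.14 and 0.11 ± 0.13, and Lgr5, the marker of crypt base stem cells, one of -0.16 ± 0.26. A second probe of Smad4 gave 0.05 ± 0.20, so the value of Smad4 differs between probes. The same holds for Bmpr1a, whose other probe gave -0.17 ± 0.16. With 3 mice per group, changes of 1.5-fold were called in only 3.5% of simulated genes.

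Interferon-stimulated genes and MHC class II genes were the lists with the largest shifts. Of 28 measured interferon genes 26 had a positive log2 change, with a median of 0.70, and of 11 measured MHC class II genes 9 did, with a median of 0.75. Ifi27l2a had a log2 change of 2.66 ± 1.14, Oas3, an antiviral oligoadenylate synthetase gene, of 1.91 ± 0.72, Cxcl9, a chemokine gene, of 1.33 ± 0.52 and Oas1a of 0.27 ± 0.12 (SE, n = 3 and 3). H2-Aa, Cd74 and H2-Eb1, components of the class II antigen presentation machinery, had log2 changes of 2.46 ± 0.81 (SE, n = 3 and 2), 1.78 ± 0.54 and 1.31 ± 0.52, and Ciita, the class II transactivator gene, of 0.99 ± 0.29. No member passed over all genes or adjusted over the list alone, and 2 and 4 members were higher at an unadjusted p under 0.05. Camera called both lists (adjusted p = 1.73e-07 and 0.00362), and neither call held with an estimated correlation (adjusted p = 0.664 and 0.498). The estimate was 0.84 for interferon genes and 0 for MHC class II genes, with unadjusted p = 0.245 and 0.0178 by that form of camera. For MHC class II the loss therefore came with the fewer degrees of freedom and not from correlation between genes. The mean of the interferon list was -0.76, -1.29 and 0.70 in wild-type replicates 1 to 3, centred between the groups, and 0.12, 0.28 and 0.81 in knockout replicates 1 to 3. Wild-type replicate 3 therefore lay above 2 of the 3 knockout arrays for interferon genes. For MHC class II genes it lay at 0.16, above 1 of them (0.07, 0.52 and 0.53). With 1 array left out the interferon median ranged from 0.32, without wild-type replicate 2, to 1.32, without wild-type replicate 3, and that of MHC class II from 0.58 to 1.13.

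**Figure D2:**
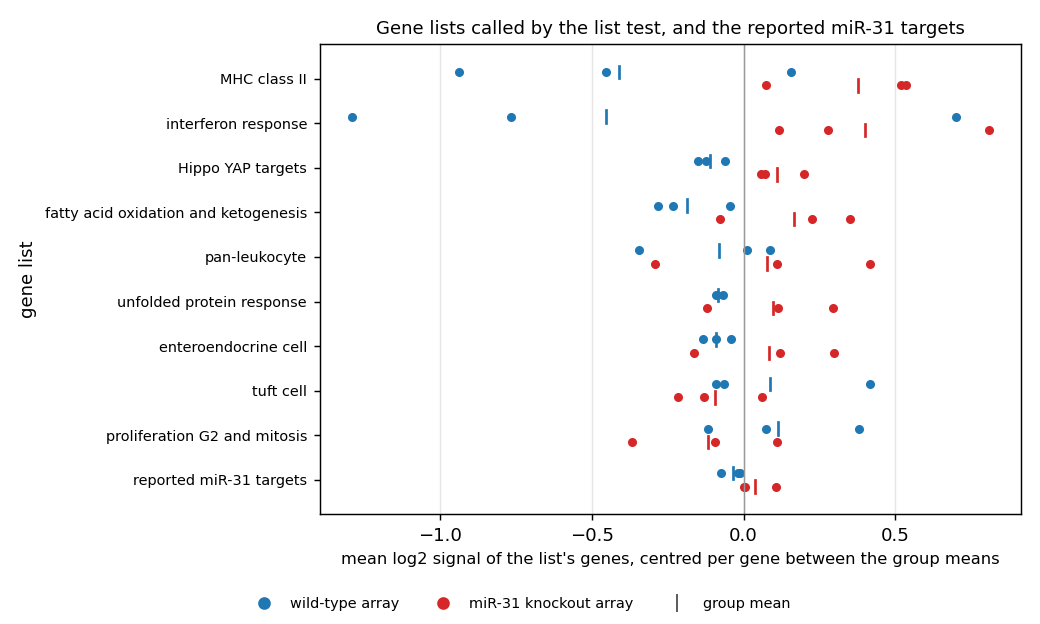
Mean log2 signal per array for the 9 gene lists called by camera and for the reported miR-31 targets, each gene centred between the 2 group means (x axis, log2 units). Points are arrays (blue wild-type, red knockout) and short vertical lines are group means; for interferon response, wild-type replicate 3 sits at 0.70 and the knockout arrays between 0.12 and 0.81.

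Other lists called by camera moved little. The list labelled fatty acid oxidation and ketogenesis had a median log2 change of 0.14 over 17 members (adjusted p = 0.00362, and adjusted p = 0.664 with an estimated correlation). Among its members Pdk4 was at 1.76 ± 0.73, Cidec at 0.98 ± 0.26 and Angptl4 at 0.91 ± 0.23. The label is that of the list and need not describe the function of each member. Hippo YAP target genes had a median of 0.16 over 17 members (adjusted p = 0.00692, and adjusted p = 0.498 with an estimated correlation), with the growth factor gene Ereg at 0.94 ± 0.24, Fjx1 at 0.36 ± 0.12, Ptpn14 at 0.43 ± 0.21 and Lats2 at 0.32 ± 0.14. The estimate for YAP targets was 0.0057, below the preset 0.01, so correlation did not remove this call either (unadjusted p = 0.0255 by that form of camera). Unfolded protein response genes had a median of 0.13 over 12 members (adjusted p = 0.0497, and adjusted p = 0.664 with an estimated correlation), with Creld2 at 0.34 ± 0.11, Ddit3 at 0.26 ± 0.16 (SE, n = 2 and 3), Chac1 at 0.54 ± 0.41 and Pdia6 at 0.15 ± 0.12. Genes of the G2 phase and mitosis had a median of -0.20 over 21 members, 18 of them below 0 (adjusted p = 0.0364, and adjusted p = 0.823 with an estimated correlation), with Cenpe at -0.46 ± 0.19, Cdca3 at -0.42 ± 0.18, Ttk at -0.51 ± 0.25 (SE, n = 2 and 3) and Bub1 at -0.40 ± 0.20 (SE, n = 2 and 2). No member of these 4 lists passed over all genes or adjusted over the list alone. The fatty acid oxidation call was lost without knockout replicate 3 (median 0.03), and the median was 0.09 without wild-type replicate 3. The YAP median was 0.10 without knockout replicate 2 and 0.31 without knockout replicate 3. The unfolded protein response call was lost under most settings, the animal number block among them, with a median of 0.05 without knockout replicate 2. The G2 and mitosis call was lost without wild-type replicate 2 (median -0.05), wild-type replicate 3 or knockout replicate 2, with the animal number block (adjusted p = 0.0548) and against the first background of all features.

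Epithelial cell type lists were mixed. Enteroendocrine genes had a median log2 change of 0.08 over 27 members and were called higher (adjusted p = 0.00692, and adjusted p = 0.664 with an estimated correlation), with the granule protein gene Chga at 0.59 ± 0.18 and the secretin gene Sct at 0.68 ± 0.23. The enteroendocrine call was lost without the filter on dim probes and without knockout replicate 1 or 2, and the median was -0.0016 without wild-type replicate 3 and 0.32 without knockout replicate 3. In the same list Isl1, a transcription factor gene, and Scg2, which encodes secretogranin 2, were lower adjusted over the list alone, with log2 changes of -0.88 ± 0.13 and -1.65 ± 0.27, and neither passed over all genes, although Isl1 did with array weights (adjusted p = 0.0419). Tuft cell genes had a median of -0.19 over 22 members (adjusted p = 0.0395, and adjusted p = 0.760 with an estimated correlation), with Dclk1 at -0.47 ± 0.16, Alox5ap at -0.31 ± 0.12, Il25 at -0.24 ± 0.11 and Gfi1b at -0.34 ± 0.19. The tuft cell call was lost without wild-type replicate 3 (median -0.03, direction turned), knockout replicate 1 or knockout replicate 3. It was also lost with array weights, the slide column or the marked spots kept, and against the first background of all features. Goblet cell genes had a median of 0.11 over 14 members and were not called (adjusted p = 0.0533), with Kcnk6 at 0.21 ± 0.11, Spdef at 0.26 ± 0.17, the mucin gene Muc2 at 0.16 ± 0.11 and Creb3l1 at 0.14 ± 0.12. The goblet list was called higher under 8 alternatives, with adjusted p from 0.0151, with the marked spots kept, to 0.0393, with quantile normalization, and its median was 0.03 without wild-type replicate 2. Surface colonocyte genes had a median of -0.05 over 20 members and a mean of -0.07, while camera gave the upward direction (adjusted p = 0.967), with Scnn1g at -0.95 ± 0.31 and Slc20a1 at -0.53 ± 0.24 (SE, n = 2 and 3), and Guca2b at 0.40 ± 0.14 and Slc51b at -0.30 ± 0.21 (SE, n = 3 and 2).

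Stem cell and signalling lists were not called. Intestinal stem cell genes had a median log2 change of -0.01 over 19 members, a mean of 0.05 and an upward direction in camera (adjusted p = 0.367), with Cd44 at 0.76 ± 0.17, Tnfrsf19 at 0.62 ± 0.26, Cdk6 at 0.33 ± 0.15 and Ephb2 at -0.24 ± 0.14. Wnt target genes had a median of -0.02 over 18 members and a mean of 0.10, with an upward direction (adjusted p = 0.359), and 2 of them, Prox1 at 1.14 ± 0.19 and Cd44, were higher adjusted over the list alone. Wif1, a Wnt inhibitor gene, had a log2 change of 0.95 ± 0.43. BMP and TGF-beta target genes had a median of -0.02 over 16 members and a mean of 0.06, with an upward direction (adjusted p = 0.504), with Smad9 at -0.53 ± 0.28, Pmepa1 at 0.48 ± 0.26, Id3 at -0.24 ± 0.13 (SE, n = 2 and 3) and Skil at 0.25 ± 0.15 (SE, n = 3 and 2). Regenerative fetal-like genes had a median of -0.04 over 16 members and a mean of 0.04, with an upward direction (adjusted p = 0.854), with Cldn4 at 0.93 ± 0.28, Il1rn at -0.48 ± 0.16, Plaur at 0.45 ± 0.25 and Il33 at -0.38 ± 0.28.

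Inflammation and position lists were not called either. STAT3 and antimicrobial genes had a median log2 change of -0.09 over 18 members (adjusted p = 0.295), with Socs3 at -0.63 ± 0.22, Lrg1 at -1.53 ± 0.74 and Socs1 at 0.38 ± 0.21. Genes of NF-kB and inflammatory cytokines had a median of 0.03 over 21 members, a mean of -0.06 and an upward direction (adjusted p = 0.453), with the neutrophil chemokine gene Cxcl5 at -2.61 ± 0.94, Ccl2 at -0.35 ± 0.11, Traf1 at 0.60 ± 0.23 and Il22 at -0.28 ± 0.12. Cxcl5 ranged from -3.78, without knockout replicate 3, where it passed (adjusted p = 0.0141), to -1.02 with normexp. Genes of proximal colon position had a median of 0.22 over 8 members and genes of distal position one of -0.30 over 7 members, all of them below 0 (adjusted p = 0.0738 for both). The proximal list was called without wild-type replicate 3, and the distal list with trend and robust variance and without wild-type replicate 2 or knockout replicate 1. Hoxb6, Osr2, Hoxb8 and Cyp2c55 had log2 changes of 0.55 ± 0.19, 0.52 ± 0.20, 0.56 ± 0.27 and 0.23 ± 0.18 (SE, n = 2 and 2 for Cyp2c55), and Hoxd9, Hoxb13, Hoxd11 and Hoxd10 of -1.24 ± 0.48, -0.30 ± 0.12, -0.44 ± 0.24 and -0.38 ± 0.30.

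Markers of other cells that the flow-separated tissue could hold were also compared. Pan-leukocyte genes had a median log2 change of 0.13 over 16 members and were called (adjusted p = 0.0497, and adjusted p = 0.823 with an estimated correlation), with Cytip at 0.75 ± 0.22 (SE, n = 2 and 2), Laptm5 at 0.37 ± 0.22, Cd37 at 0.25 ± 0.19 and Srgn at 0.38 ± 0.33. The call was lost without wild-type replicate 2 (median 0.05), knockout replicate 2 or knockout replicate 3 (median 0.01) and under most other settings, and the median was 0.31 without knockout replicate 1. In the myeloid list of 20 members, with a median of 0.03 (adjusted p = 0.159), the mucosal mast cell protease gene Mcpt2 rose by a log2 change of 2.10 ± 0.13 (SE, n = 3 and 2, adjusted p = 0.00547), a call lost without wild-type replicate 1 (adjusted p = 0.0523). Cpa3, mast cell carboxypeptidase, at 2.14 ± 0.28, and Mcpt1, at 2.46 ± 0.43 (SE, n = 3 and 2), were higher and C1qb, at -0.53 ± 0.13, was lower adjusted over the list alone, and none of the 3 passed over all genes. Under 5 alternatives Cpa3 did pass (adjusted p from 0.0162 to 0.0441), as did Mcpt1 under 2. T and NK cell genes had a median of 0.03 over 27 members (adjusted p = 0.325), with Prf1 at -0.35 ± 0.17, Cd4 at -0.27 ± 0.20, Cd7 at 0.40 ± 0.31 and Cd8a at 0.24 ± 0.22. The T and NK cell list was called higher without wild-type replicate 3 or knockout replicate 1. B and plasma cell genes had a median of 0.24 over 13 members (adjusted p = 0.0738), with Jchain at 1.20 ± 0.24 higher adjusted over the list alone, Blk at 0.58 ± 0.23, Pou2af1 at 0.34 ± 0.14 and Derl3 at 0.51 ± 0.26. The B and plasma cell list was called higher under 5 alternatives, with adjusted p between 0.0040 and 0.0475.

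Several lists were measured only in part. The test held 20 of 34 surface colonocyte, 14 of 22 goblet cell, 12 of 26 tight junction and 12 of 20 unfolded protein response genes. Over all 39 lists, camera called 7 higher and 2 lower, and adjusted p-values of the other 30 ranged from 0.0533 to 0.967. With an estimated correlation and with fry, 0 lists were called. An unadjusted p under 0.05 remained for 2 lists with an estimated correlation, MHC class II and Hippo YAP targets, and for 1 with fry, Hippo YAP targets, against 16 for camera.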

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

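Keeping the spots marked as outliers and the animal number block were tests chosen after the results were seen, as was the list background of features with a symbol, which replaced all features. With normexp and quantile normalization 70 genes were higher, and 115 and 51 were 2-fold higher and lower at an unadjusted p under 0.05. Without a filter on dim probes 6 genes were lower, 379 and 414 were 2-fold higher and lower, and 4 lists were higher. With the filter requiring all 6 arrays, which tests fewer genes, 25 were higher, 8 lower, and 144 and 77 were 2-fold higher and lower. Trend and robust variance gave 70 higher and 34 lower genes and 4 lower lists, and array weights gave 64 higher and 40 lower genes. The slide column as a random block left 1 lower list, and the first list background, of all features, 0 lower lists, so both lower lists rest on the later background. Wild-type replicate 3 and knockout replicate 3, whose animal numbers lie apart from the others' and from each other, were at -22.1 and -41.5 on the second principal component (24.3% of the variance), with the other 4 arrays between 7.06 and 35.3. These arrays also lay in slide columns 4 and 3, and 4.82% and 7.36% of their spots were non-uniform, against 12.7% to 17.2% on the others. Animal number, slide column and marked spots cannot be told apart here. With the animal number block 48 genes were higher and 14 lower, 50 of them shared with the fit without it, and 6 lists were higher and 1 lower. With an estimated correlation and with fry, 0 lists were higher and 0 lower. Leaving out 1 array gave 18 to 67 higher and 4 to 49 lower genes, 184 to 352 and 167 to 360 genes 2-fold higher and lower, 4 to 9 higher and 1 to 2 lower lists, and a median of the reported targets between 0.04 and 0.10, with fewer mice in each fit. Apart from the fewer genes and mice, the cause was not tested. Reported targets kept a positive median under every alternative, up to 0.11, and were never called, with adjusted p between 0.053 and 0.779. The surface colonocyte list changed direction in camera or fry, with a median of -0.046 without the filter on dim probes, with the filter requiring all 6 arrays and with fry, of -0.052 with array weights, of -0.050 with the animal number block and of -0.12 with the marked spots kept. Leaving out 1 array gave it -0.061 to 0.0003, with the direction changed without wild-type replicates 2 and 3 and knockout replicates 1 and 3. The regenerative list changed direction with fry, at -0.042, and without wild-type replicate 1, at 0.0008, and knockout replicate 3, at -0.099, within a range of -0.13 to 0.071 over the arrays left out. The T and NK cell list changed without wild-type replicate 2, at -0.093, and knockout replicate 3, at -0.16, with a range of -0.16 to 0.26. The tuft cell list changed without wild-type replicate 3, at -0.034, with a range of -0.27 to -0.034. With the mean of a gene's probes, Bmpr1a was at -0.032, Skil at -0.81 and Ephb2 at 0.017. Leaving out 1 array gave Il17ra -0.069 to 0.27, Gsk3b -0.018 to 0.094 and Lgr5 -0.42 to 0.11. Of the 20 named genes called, Zfp979, Ifi202b, Zfp981, Afm, Cma2 and Zfp963 kept the call under every alternative that tested them. Zfp600 lost it with the marked spots kept, at 0.32, where a brighter probe was used. No paired analysis was possible because no replicate or animal number is shared between the groups. The test of genes with a miR-31 seed site was not run for lack of 3' UTR sequences. Signal over background limits the dim genes: 13 called features were not well above background on any wild-type array and 7 on any knockout array.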

Other observations

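The tests of clustering, of leukocytes, of variation between mice and of other groupings were chosen after the results were seen, whereas those on mast cells were written before the values outside chromosome 14 were seen. None of the remaining gene groups, nor the neighbours of Mir31 described above, was called by camera in the fit of the report. Cholesterol synthesis was called lower under 6 alternatives (adjusted p from 0.0108 to 0.0393), endothelium and blood lower under 2, adipocyte genes higher under 3 and S phase higher without wild-type replicate 2. Median log2 changes were 0.24 for adipocyte genes, -0.18 for endothelium and blood, -0.15 for cholesterol synthesis, 0.02 for tight junction and adhesion, 0.01 for deep crypt secretory and Paneth genes, -0.01 for ribosomal protein genes, 0.01 for S phase and -0.01 for neuron and glia. They were 0.09 for small intestine, 0.06 for immediate early and dissociation stress, -0.09 for fibroblast, -0.04 for smooth muscle, 0.01 for the neighbours of Mir31, 0.02 for xenobiotic and glutathione metabolism, -0.02 for hypoxia and glycolysis and -0.0029 for circadian clock genes. The median and the direction of camera differ in sign for ribosomal protein, fibroblast and hypoxia genes, with means of 0.0068, 0.07 and -0.04. For small intestine and xenobiotic genes the means of -0.0038 and -0.04 differ from an upward camera direction, and for the neighbours of Mir31 the mean of -0.29 and the downward direction differ from the median. Among deep crypt secretory and Paneth genes, Itln1, at 0.90 ± 0.20, and Mmp7, at 1.37 ± 0.37, were higher adjusted over the list alone and did not pass over all genes. Beyond the named genes, calls outside the rule, picked after their values were seen, were Mcpt4, a mast cell chymase gene, at a log2 change of 2.36 ± 0.20, Agmat at 2.15 ± 0.18 and Rab3b at 2.35 ± 0.24.

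Called genes lay close to one another. Of 33 called genes with a symbol, 15 had another called gene within 10 tested genes, against a median of 2 and at most 10 in 10000 random sets (permutation p = 1e-04, the smallest these sets can give). Chromosome segments that differ between the groups of mice, such as those of another strain around the deleted locus or elsewhere, are a candidate explanation, and related genes whose probes share sequence are another. The counting was revised after its result had been seen: with related neighbours counted once, 6 of 26 had a called neighbour (permutation p = 0.0225), and with genes lacking a proper name dropped as well, 4 of 23 did (permutation p = 0.0856). For genes at least 2-fold apart the same 3 countings gave permutation p = 0.0004, 0.0988 and 0.1234, and without the called genes 0.0037, 0.195 and 0.1981. Shared sequence would move neighbours the same way. The 4 genes left in the strictest counting were S100z near F2r, at log2 changes of -1.52 and 2.71, and Hebp1 near Pbp2, at 1.61 and -3.57. Their opposite directions argue against shared sequence for these pairs, whose number could arise by chance. For the other clustered genes, differing segments and shared sequence cannot be told apart. The segment around Mir31 alone is argued against, because 24.2% of the called genes (95% exact interval 11.1% to 42.3%) lie anywhere on chromosome 4. That interval counts neighbouring genes as independent. On this chromosome only Acer2 and Rab3b lie within 78 tested genes of Mir31, and the other called genes lie 487 to 605 away.

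Of the mast cell proteases clustered on chromosome 14, Cma2, Mcpt2 and Mcpt4 were called, with a median log2 change of 2.36. More mast cells in the knockout samples may account for this, or a chromosome 14 segment that differs between the groups. Mast cell genes on other chromosomes had a median log2 change of 0.24 over 6 genes (95% bootstrap interval -0.25 to 1.41). Cpa3 was at 2.14, Fcer1a at 0.69, Hdc at 0.25, Gata2 at 0.24, and Slc18a2 and the abundant tryptase gene Tpsb2 at -0.25. The bootstrap resampled genes, so its interval does not measure spread between mice. Hdc and Gata2, which set the median, had group means from -6.95 to -6.60. The lowest signals of probes well above background were -7.13 to -6.12 per array, so changes of these dim genes may be understated. In the cluster 6 of 8 measured genes had a positive log2 change, with Ctsg and Gzmb at 0.12 and 0.13, Cma1 at -0.60 and Mcpt9 at -0.54. The interval spans 1.18, which is the called proteases' median divided by a factor that the test set in advance, so the 2 explanations cannot be told apart, and Cpa3, on chromosome 3, would not follow from a chromosome 14 segment.

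Interferon and MHC class II genes were higher in knockout tissue on average, with wild-type replicate 3 above 2 of the 3 knockout arrays for interferon genes and above 1 for MHC class II genes. For interferon genes, an even rise of all leukocytes alone is argued against. The pan-leukocyte median of 0.13 (95% bootstrap interval 0.04 to 0.25) lies below the interferon median of 0.70, as it does with any array left out (0.01 to 0.31 against 0.32 to 1.32). The bootstrap resampled genes, whose estimated correlation was 0.78, so its interval does not measure spread between mice. A change in only some leukocytes was not tested, and MHC class II genes were not compared in this way. Variation between mice that does not follow genotype stays open: 3 of the 10 splits of the 6 arrays into 3 and 3, the real one included, gave an interferon median at least as large, with 1.34 as the highest of the others, and 2 of 10 did so for MHC class II, at 0.75 and 0.86. For both lists, knockout replicates 1 and 2 lay above wild-type replicates 1 and 2. Knockout replicate 3 lay above wild-type replicate 3, at 0.81 against 0.70 for interferon genes and 0.53 against 0.16 for MHC class II genes. The latter are 1 mouse per genotype, and their animal numbers lie far apart. Among the 6 splits with wild-type replicate 3 and knockout replicate 3 on opposite sides the real one gave the largest medians, with 0.66 and 0.51 as the highest of the others. These splits are too few to tell genotype from mouse.

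With 10 splits of the 6 arrays, a share under 0.05 cannot be reached. The real grouping called 58 genes, against at most 1 in any other split, and gave 426 genes at least 2-fold apart at an unadjusted p under 0.05, against at most 264, so that in each case 1 split, the real one, reached the real count. For gene lists, 5 of the 10 splits called at least as many as the 9 of the real grouping, with up to 13 in another split, so the number of lists called does not exceed what other groupings of these mice give.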
